A study of Sus scrofa with 22 samples.

How the data were processed

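RNA sequencing was available for 22 pig libraries in 6 groups. There were 5 libraries of foliate papillae, the folds at the side of the tongue that carry taste buds, and 5 of passage 1 organoids grown from papilla cells of the same pigs. A further 3 organoid libraries in LPM, the growth medium, stood beside 3 in LPM without FGF10, and 3 more in LPM stood beside 3 finished in CQ. The abbreviations LPM and CQ are not spelled out, and the composition of CQ is not given, in the sources used here. Per the labels' protocols, LPM held EGF at 50 ng/ml, FGF10 at 100 ng/ml, FGF2 at 10 ng/ml, R-spondin 2 at 500 ng/ml, noggin, SHH and Wnt3a at 100 ng/ml each, insulin at 10 nM, CHIR99021 at 2.5 µM, A83-01 at 0.5 µM, forskolin at 1 µM and prostaglandin E2 at 20 nM. CQ cultures were in LPM from day 0 and in CQ from day 10 to day 16 or 17, per the labels. No day is recorded for the LPM libraries beside them, so culture age cannot be told apart from the medium.

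Per the labels' protocols, organoids were freed from their matrix on ice and lysed for a column RNA kit, whereas papillae were extracted with a different low-input kit and no DNase step, so the kit cannot be told apart from the contrast of tissue and organoids. Messenger RNA was selected with poly-T beads, and whether libraries were directional is not given in the sources used here. The submitters' processing notes name FastQC 0.11.9, STAR 2.7.10b, MultiQC 1.14, featureCounts and DESeq2. Each deposited file holds whole-number counts of read pairs per gene, made by the authors with featureCounts and not normalized. Per the file headers, featureCounts 2.0.3 was used for 16 libraries with 27376 genes and 2.0.6 for the 6 libraries of the CQ experiment with 29851 entries. Also per the file headers, strand was ignored, a read pair overlapping several genes counted for each, and pairs that mapped to several places were not counted. Reads of a gene and of one antisense to it or overlapping it can therefore not be told apart, and levels are uncertain for members of near-identical families, such as the BPIF, S100A, keratin and SLA genes. In the CQ experiment 1 entry without a gene name took 0.326 to 0.477% of the counts per library and was left out of library sizes and tests, leaving 29850 genes. Of the genes, 26838 were in both annotations, 26756 of them with the same start and end. Coordinates are those of the deposited files, which use Sscrofa11.1 positions, and 26862 of 27376 and 29850 of 29851 symbols matched the reference gene table. The keratin gene KRT13 had no entry under that symbol.

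Library totals ranged from 14.67 to 27.77 M counts and together came to 459 M. A group in which a gene had 0 counts was given a floor of 3 counts over the whole group, and such folds, taken between counts summed over each group and divided by its TMM-scaled total, are written as "at least". For the CQ group the floor was 38.2 counts, a choice made after the data were seen. It rests on an estimate of 12.73 reads per molecule. That estimate is the median ratio of variance to mean over the CQ libraries, for genes with a mean of 10 to 30 counts. Any other difference between these libraries also enters it, so it is not a direct measure. Where a ratio is given for a group with 1 to 3 counts, it has its exact 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

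Groups, comparisons, gene lists, the rule for named genes and the alternatives listed below were fixed before the data were examined, and 3 further alternatives for CQ were added afterwards. Each comparison was fitted on its 2 groups alone with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg adjustment over all genes tested), and a gene was called at an adjusted p under 0.05. CPM are TMM-scaled, and fold changes and standard errors come from the fit. Gene lists (41 in 6 themes, covering taste, epithelium, other cell types, hormones, pathways and processes) were tested 2-sided with limma 3.58.1 camera on voom values at a preset correlation of 0.01, where at least 3 members passed the filter. Of 665 listed genes 627 were in the files. The same lists were tested with an estimated correlation and with fry, which asks whether members move on balance in 1 direction and makes no comparison with other genes. Sets of 500 genes with the smallest p among those higher, and among those lower, in organoids than in papillae were tested in both media comparisons.

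Named genes were chosen by rule. A fixed set was always named (INS, TRPM5, PLCB2, GNAT3, TAS1R3, PKD2L1, ENTPD2, LGR5, LGR6, SOX2, SHH, KRT5, KRT8, KRT13, MKI67, FGFR2, SPRY4, DUSP6, AXIN2 and GLI1). Added to it were the 6 highest and 6 lowest called genes with an average log2 CPM of at least 3 and no overlap between groups, and up to 2 called members per list and direction by smallest p, or the most abundant member where no member was called. For organoids against papillae every measured member of the insulin processing and beta cell factor lists was eligible. Examples were drawn from these.

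Pig numbers name the same animals in papillae and organoids, so these libraries are paired. Deviations from the group means correlated at 0.0323, 0.0517, 0.0805, 0.0721 and 0.0918 between the libraries of pigs 1 to 5. The highest values of these papillae with organoids of another pig were 0.0888, 0.0281, 0.0564, 0.0226 and 0.0867. Papillae of pig 1 and organoids of pig 2 thus matched another animal best. The fit with the pig as a block was an alternative and is given beside results whose call it changed. The FGF10 libraries are labelled as biological replicates, without saying whether these were separate cultures or animals, and the CQ labels say neither, so p-values in both media experiments measure the spread between these libraries. No pair of replicates agreed within sampling noise when read pairs were taken as independent. Chi-square per degree of freedom was 2.57 to 4.64 within the arms of the FGF10 experiment. It was 5.89 to 52.05 in the LPM and 16.26 to 18.82 in the CQ libraries of the CQ experiment, where repeated reads of the same molecules would raise it. Between pigs it was 76.21 to 284.7 in papillae and 31.96 to 236 in organoids. P-values in the FGF10 experiment therefore measure a spread well below that between animals.

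Alternatives were DESeq2's size factors, library size alone, no filter, a stricter filter, DESeq2 1.42.0, limma-voom, a fit of all 6 groups, removal of mitochondrial and the 50 most abundant genes, the replicate block, and leaving out each library in turn. Added for CQ were removal of the ribosomal scaffold with abundant genes, counts per estimated molecule, and abundant genes alone. The procedure was tested on simulated data with 200 changed genes among the tested ones. It called 40.8% of genes changed by a fold of 2 and 85.4% of those changed by a fold of 4 for organoids against papillae (16311 genes), 86% and 100% for LPM without FGF10 (14262 genes), and 54% and 68.1% for CQ (13827 genes). Calls among unchanged genes numbered 4 of 15977, 11 of 13935 and 2 of 13237. These rates hold for a setting in which few genes change. In the data 67.5% of tested genes were called for organoids against papillae and 47.9% for CQ. The simulated rates therefore do not carry over to those 2 comparisons.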

Results

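Foliate papillae of 5 pigs had 17.04 to 20.71 M counts per library and the passage 1 organoids of these pigs 21.79 to 27.77 M. In the FGF10 experiment the 3 LPM libraries held 20.77 to 25.23 M counts and the 3 without FGF10 19.64 to 23.45 M. In the CQ experiment the 3 LPM libraries held 19.62 to 26.01 M and the 3 CQ libraries 14.67 to 16.0 M. Genes with at least 1 count numbered 20256 to 21149 per papilla library, 17907 to 19049 in passage 1 organoids, 17693 to 17834 in both groups of the FGF10 experiment, 17489 to 17920 in the LPM libraries of the CQ experiment and 14014 to 16005 in the CQ libraries. The 10 most abundant genes took 24.8 ± 7.91% of counts in papillae and 5.86 ± 0.467% in passage 1 organoids (SD, n = 5 each).

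The series title states that the organoids synthesize insulin. The insulin gene INS (chromosome 2, 1496842 to 1498052) had 0 counts in 22 of 22 libraries. Over each group this allows at most 0.0347 CPM in papillae, 0.0228 CPM in passage 1 organoids, 0.0435 and 0.0474 CPM with and without FGF10, 0.0464 CPM in the LPM libraries of the CQ experiment and 0.811 CPM in the CQ libraries. These bounds hold for read pairs the counting could assign to the gene. Pairs that mapped to several places were not counted, and neither raw reads nor protein were analysed here. PDX1, NEUROD1 and NEUROG3, transcription factors of the pancreatic endocrine lineage, also had 0 counts in the 10 libraries of papillae and passage 1 organoids. Other listed beta cell factors were detected there. MAFA had 118 counts in papillae and 50 in these organoids, and NKX6-1 had 301 and 4.

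Organoids were compared with the papillae they came from to describe how their gene expression differed. With the preset correlation, the lists of type I and type III taste cells and of gland, muscle, fibroblast, endothelial, immune and nerve cells were called lower in organoids, and those of taste bud epithelium and glycolysis higher. None of these calls held with an estimated correlation (adjusted p = 0.152 for type I, 0.437 for type III and 0.329 for taste bud epithelium and for glycolysis). TRPM5, the cation channel of sweet, umami and bitter transduction (chromosome 2, 1646597 to 1664935), fell 8.98-fold, from 20.0 ± 10.9 to 2.22 ± 0.700 CPM (SD, n = 5 each; log2 fold change -3.17, SE 0.41, adjusted p = 4.17e-05). SOX2, a transcription factor of taste progenitors (chromosome 13, 119668476 to 119669435), rose 4.35-fold, from 66.3 ± 6.61 to 288 ± 128 CPM (SE of log2 0.27, adjusted p = 3.23e-05). Of 16311 genes tested, 11011 were called, 5281 higher and 5730 lower in organoids, and 2383 of the higher and 4413 of the lower changed at least 2-fold.

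All 6 tested members of the type I (glia-like) taste cell list fell (camera adjusted p = 0.0156, and 0.152 with an estimated correlation). ENTPD2, the ectonucleotidase that clears ATP around taste cells, fell 7.80-fold from 57.3 ± 30.2 CPM (n = 5, adjusted p = 0.000101), and the glutamate transporter gene SLC1A3 had 642 counts in papillae and 3 in organoids, a ratio of 325 (95% interval 111 to 1581). Of 13 type II (sweet, umami or bitter) members 6 fell and 1 rose, or 5 and 1 when adjusted over the list alone, and the list was not called (adjusted p = 0.211). PLCB2, the phospholipase downstream of taste receptors, fell 16.6-fold from 22.99 ± 10.87 CPM (adjusted p = 6.59e-05), and the G protein subunit gene GNB3 fell 20.9-fold. GNA14, which encodes a Gq-family subunit, rose 2.95-fold (adjusted p = 0.00696). GNAT3, the gustducin alpha subunit, was at 2.89 ± 2.10 and 1.99 ± 0.759 CPM (adjusted p = 0.525). Of 9 type III (sour, presynaptic) members 7 fell (adjusted p = 0.0156, and 0.437 with an estimated correlation). NCAM1 went from 1744 counts to 3 (ratio 884, 302 to 4289) and SCG2 from 2010 to 3 (ratio 1018, 348 to 4943), and both are also neuronal genes, in libraries where 13 of 15 nerve and Schwann cell markers fell as well. PKD2L1, a channel of sour cells, was at 0.743 ± 0.518 and 0.818 ± 1.41 CPM (adjusted p = 0.916). TAS1R3, the shared subunit of sweet and umami receptors, fell 1.89-fold from 60.4 ± 10.2 to 32.0 ± 6.04 CPM (adjusted p = 0.000374), and each of 13 bitter receptor genes had at most 49 counts over the 5 papilla libraries and was not tested.

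**Figure D1:**
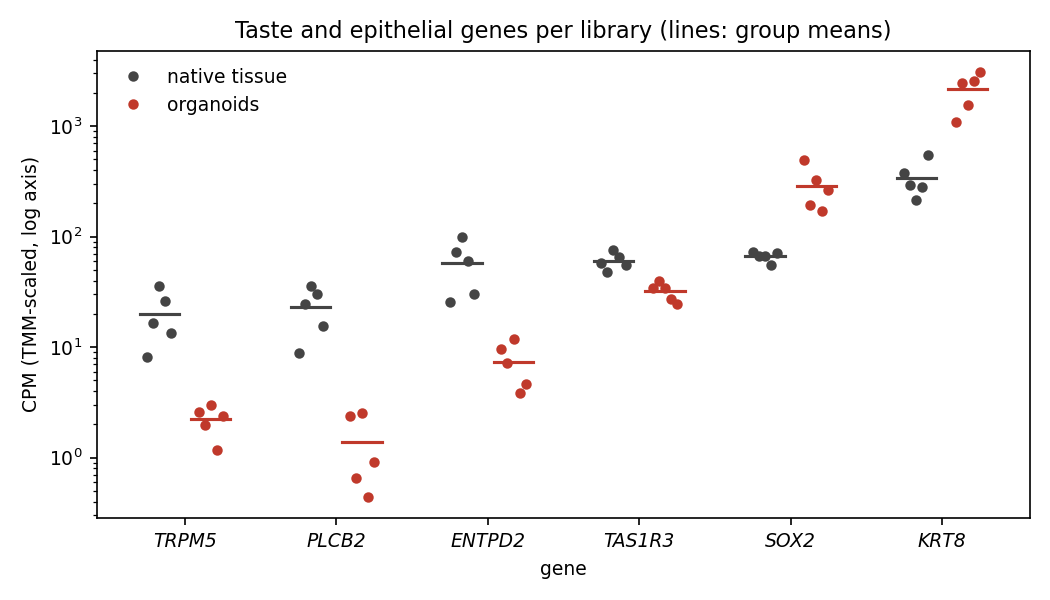
Levels of TRPM5, PLCB2, ENTPD2, TAS1R3, SOX2 and KRT8 in papillae (grey) and passage 1 organoids (red), in CPM on a log axis, with 1 dot per library (5 per group) and a line at each group mean. The dots of the groups do not overlap for these 6 genes, with the first 4 lower and SOX2 and KRT8 higher in organoids.

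In the taste stem and progenitor list 6 of 12 members rose and 2 fell, or 7 and 2 when adjusted over the list alone, and the list was not called (adjusted p = 0.266). SOX9 rose 4.99-fold to 188 ± 34.8 CPM (n = 5, adjusted p = 4.35e-06), while PROM1, a progenitor surface marker, fell 21.5-fold from 12.5 ± 2.90 CPM (adjusted p = 5.58e-07). LGR5, the R-spondin receptor of stem cells in the posterior tongue, was at 1.28 ± 0.716 CPM in papillae and had 2 counts over the 5 organoid libraries, a ratio of 86.6 (23.4 to 724). Its relative LGR6 was at 20.3 ± 6.98 and 65.9 ± 72.3 CPM (adjusted p = 0.051); over 19 alternatives its p ranged from 0.00933 to 0.31, with 0.0175 and 0.0156 without the organoids of pig 1 or pig 3. Of 10 taste bud epithelium genes 7 rose and 2 fell, or 8 and 2 over the list alone (adjusted p = 0.0211, and 0.329 with an estimated correlation). These included the simple keratins KRT8, from 341 ± 127 to 2157 ± 809 CPM (6.33-fold, adjusted p = 3.62e-05), KRT19 (10.8-fold) and KRT7 (6.08-fold). Basal epithelium genes divided, with 7 of 11 higher, such as the integrin gene ITGA3 (5.39-fold) and the laminin gene LAMB3 (4.33-fold), and 4 lower. KRT5 fell 4.83-fold from 8182 ± 1282 CPM (adjusted p = 8.2e-06) and KRT15 6.37-fold. Of 17 suprabasal and cornified genes 16 fell (adjusted p = 2.35e-06, and 0.122 with an estimated correlation), among them CNFN, a cornified envelope gene (626-fold, from 1028 ± 374 CPM), and the desmosome gene DSG1 (375-fold).

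Of the 11 tested genes of insulin processing and secretion 8 fell and 1 rose, and the list was not called (adjusted p = 0.0639); it was called with library size alone (0.0409) and without papilla 1 (0.0367) or any 1 organoid library (0.033 to 0.0473). ABCC8 and KCNJ11, neighbours on chromosome 2 that encode the subunits of the ATP-sensitive potassium channel, fell 19.4-fold from 8.27 ± 3.03 CPM (n = 5, adjusted p = 0.000104) and 3.59-fold from 16.8 ± 6.33 CPM (adjusted p = 0.0178). The carboxypeptidase gene CPE, which trims prohormones, fell 5.07-fold, SCGN 43.5-fold and the synaptic vesicle gene VAMP2 2.46-fold. RIMS2, an exocytosis scaffold, rose 4.68-fold to 7.51 ± 0.641 CPM (adjusted p = 7.69e-05). PCSK1, the prohormone convertase, had 65 counts in papillae and 16 in organoids, and was not tested. Nerve and muscle markers fell in the same libraries. Of 8 tested beta cell transcription factors 4 rose and 3 fell; the median log2 fold change was 0.32, the mean was -1.93 and the test pointed down (adjusted p = 0.78). FOXA2 rose 2.95-fold to 109.6 ± 29.3 CPM (adjusted p = 4.06e-05) and INSM1 4.49-fold to 4.88 ± 3.92 CPM (adjusted p = 0.0217). The INSM1 call was lost with the pig as a block (0.0824), with limma-voom (0.086) and without the organoids of pig 5 (0.0599), over a range of 0.0053 to 0.086. RFX6, an endocrine factor, went from 4434 counts to 2 (ratio 3369.9, 932 to 27835).

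Markers of other tissues of the tongue fell almost throughout. OBP2B, an odorant-binding lipocalin gene (chromosome 1, 272886871 to 272890537), fell from 52884 ± 29083 to 0.603 ± 0.391 CPM (log2 fold change -16.40, n = 5, adjusted p = 1.27e-07), and BPIFA2 went from 3492574 counts to 3. All 8 tested gland genes fell (camera adjusted p = 0.00231, and 0.259 with an estimated correlation), as did 21 of 21 skeletal muscle genes (0.000269, and 0.513 estimated), 17 of 18 fibroblast and matrix genes (6.54e-07, and 0.219 estimated), 14 of 15 endothelium and pericyte genes (4.24e-07, and 0.093 estimated), 17 of 21 immune genes with 2 rising, or 18 falling over the list alone (1.2e-05, and 0.122 estimated), and 13 of 15 nerve genes with 1 rising (0.000468, and 0.219 estimated). MYH2, a fast muscle myosin, was at 494 ± 488 CPM in papillae and at 0 in organoids, at least 21979-fold lower. DCN of fibroblasts fell 5531-fold from 326 ± 97.3 CPM, PECAM1 of endothelium 44.4-fold from 107 ± 8.29 CPM, and SOX10 of Schwann cells 1177-fold from 123 ± 29.0 CPM. The libraries also differed in ribosomal RNA: RN5-8S, a ribosomal RNA gene, fell 17.2-fold from 342 ± 83.03 CPM (adjusted p = 9.03e-06).

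Among pathway lists, 14 of 20 FGF and ERK targets rose and 2 fell (adjusted p = 0.00192, and 0.253 with an estimated correlation). PHLDA1 rose 17.9-fold to 464 ± 139 CPM (n = 5, adjusted p = 8.18e-08) and DUSP6, a phosphatase that limits ERK, 1.91-fold (adjusted p = 0.00177), while SPRY4 was at 13.9 ± 0.448 and 17.7 ± 12.3 CPM (adjusted p = 0.517). The receptor gene FGFR2 fell 3.12-fold from 31.8 ± 2.80 CPM (adjusted p = 0.000294). Of 11 Hedgehog genes 7 fell and 1 rose (adjusted p = 0.0173, and 0.152 estimated). The target gene GLI1 fell 169-fold from 9.83 ± 4.92 CPM, whereas the ligand gene SHH rose 11.2-fold to 75.0 ± 47.5 CPM (adjusted p = 0.0026). Of 15 BMP and TGF-beta targets 13 fell and 1 rose (adjusted p = 0.000178, and 0.122 estimated). Fibroblast and vessel markers fell together with both lists.

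Of 17 Wnt targets 7 rose and 7 fell, with a median of 0.01, a mean of -1.39 and a test pointing up (adjusted p = 0.976). AXIN2 rose 2.39-fold to 32.7 ± 18.9 CPM (adjusted p = 0.00576) and ZNRF3 2.95-fold. Of 21 glycolysis and hypoxia genes 19 rose (adjusted p = 6.93e-07, and 0.329 estimated), including PKM (4.77-fold, to 2729 ± 616 CPM) and the vasoactive peptide gene ADM (43.6-fold). Of 14 p53 and apoptosis genes 11 rose and 1 fell (adjusted p = 0.000178, and 0.259 estimated), including BAX (5.10-fold) and CCNG1 (5.75-fold). Of 25 interferon genes 15 fell and 3 rose (adjusted p = 0.00499, and 0.437 estimated), among them HERC6 (20.4-fold lower). Immune and endothelial markers fell in the same libraries. Of 13 cAMP targets 11 fell and 1 rose (0.0211, and 0.219 estimated), among them the clock gene PER1 (5.75-fold lower). Of 20 cholesterol synthesis genes 11 rose and 1 fell (0.0446, and 0.615 estimated); this call was lost without papilla 4 (0.0537) or the organoids of pig 4 (0.151) and with library size alone (0.0589). In the cell cycle list 6 of 28 genes rose, or 3 over the list alone; it was not called (adjusted p = 0.222) but was with the pig as a block (0.044). Without the organoids of pig 4 its direction turned down (0.928). MKI67, a proliferation marker, was at 42.5 ± 6.60 and 71.1 ± 119.1 CPM (adjusted p = 0.48), and without that library its log2 fold change was -1.21 (0.0531, in a range of 0.0531 to 0.576).

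Where not given, counts adjusted over a list alone were the same as those over all genes, and with an estimated correlation limma camera called 0 of the 39 lists tested, against 18 with the preset value and 34 by fry. Lists that fry called and camera with the preset value did not included type II cells, stem and progenitor cells, insulin processing and beta cell factors. With library size alone the median of all genes moved from -0.01 to 0.28 on the log2 scale and 59.6% in place of 48.0% of called genes were higher in organoids (6771 higher and 4592 lower), so directions near that shift depend on the scaling.

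The FGF10 experiment asked what removing this ligand from the medium changed, in 3 libraries per arm. Changes were small, and the lists of secretory epithelium and oxidative stress were called lower with the preset and with an estimated correlation. With an estimated correlation and the replicate block together neither was called (camera adjusted p = 0.259 for both). Other called lists, among them cell cycle, suprabasal epithelium, taste stem and progenitor cells, Wnt targets and taste bud epithelium, lost their calls with the estimated correlation (adjusted p = 0.34, 0.0723, 0.11, 0.39 and 0.34), and those of type I, II and III taste cells were not called. C14H10orf99, a mucosal peptide gene (chromosome 14, 85404074 to 85421474), was the most reduced called gene with an average log2 CPM of at least 3, from 46.5 ± 3.90 to 21.3 ± 3.38 CPM (SD, n = 3 each; 2.19-fold, log2 fold change -1.13, SE 0.08, adjusted p = 9.12e-09). INSM1, a transcription factor of neuroendocrine differentiation, rose 1.77-fold from 6.91 ± 0.627 to 12.2 ± 1.36 CPM (SE 0.11, adjusted p = 4.43e-05). Of 14262 genes tested 254 were called, 83 higher and 171 lower without FGF10, 7 of them changed at least 2-fold, and the median size of a called log2 change was 0.30.

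Of 9 tested simple and secretory epithelium genes 6 fell, or 8 adjusted over the list alone (camera adjusted p = 2.73e-20, and 0.0376 with an estimated correlation). The mucin genes MUC20 and MUC4 fell 1.59-fold, from 42.3 ± 0.663 to 26.6 ± 0.292 CPM (n = 3, adjusted p = 6.36e-08), and 1.37-fold (adjusted p = 1.4e-07). Of 15 oxidative stress and xenobiotic genes 5 fell, or 10 over the list alone (1.44e-12, and 0.0376 with an estimated correlation), led by the quinone reductase gene NQO1, from 146 ± 10.7 to 93.3 ± 8.36 CPM (1.57-fold, adjusted p = 7.94e-08). Of 12 suprabasal and cornified genes 4 fell, or 6 over the list alone (2.89e-09, and 0.0723 estimated). KRT4 fell 1.73-fold from 410.4 ± 37.3 to 237 ± 37.7 CPM (adjusted p = 1.52e-07), and the calcium-binding alarmin genes S100A8, S100A9 and S100A12 fell 1.74-fold, 1.61-fold and 1.70-fold. The serine protease gene PRSS27 fell 1.73-fold and FAM3D 1.85-fold. Among genes that rose were the cell adhesion gene CHL1 (1.73-fold, to 16.5 ± 0.334 CPM, adjusted p = 3.15e-06), the growth factor gene IGF1 (1.71-fold), NEURL1 (1.54-fold) and AQP3, a water and glycerol channel (1.55-fold, to 52.4 ± 2.81 CPM, adjusted p = 9.05e-07).

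In the taste stem and progenitor list 2 of 11 members rose, or 4 over the list alone (adjusted p = 0.000227, and 0.11 with an estimated correlation). SHH rose 1.29-fold, from 135 ± 6.33 to 174 ± 5.04 CPM (n = 3, adjusted p = 5.06e-06), while SOX2 was at 419 ± 7.79 and 437 ± 4.07 CPM (adjusted p = 0.536) and LGR6 at 41.5 ± 4.28 and 39.9 ± 8.72 CPM (0.886). Of 13 Wnt targets 2 rose, or 6 with 1 falling over the list alone (0.00242, and 0.39 estimated); NOTUM, a feedback inhibitor of Wnt, rose 1.44-fold (adjusted p = 3.22e-05) and AXIN2 was at 34.4 ± 2.39 and 38.4 ± 1.87 CPM (0.244). Of 10 taste bud epithelium genes 1 fell, or 4 over the list alone (0.00285, and 0.34 estimated), with KRT8 at 1773 ± 17.9 and 1795 ± 16.7 CPM (0.919). TRPM5 was at 2.67 ± 0.482 and 2.92 ± 0.492 CPM (adjusted p = 0.874), GNAT3 at 1.88 ± 0.213 and 1.91 ± 0.274 CPM (0.977), TAS1R3 at 25.0 ± 1.41 and 25.8 ± 1.42 CPM (0.841), PLCB2 at 1.15 ± 0.244 and 1.33 ± 0.418 CPM (0.847) and ENTPD2 at 10.2 ± 0.0835 and 10.99 ± 0.592 CPM (0.719). The lists of type I, II and III cells were not called (0.731, 0.236 and 0.397), although 2 of 10 type II genes rose when adjusted over the list alone. PKD2L1 had 34 and 51 counts (0.52), LGR5 had 0 counts in both arms and GLI1 had 0 and 2.

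The FGF and ERK target list was not called (adjusted p = 0.731), with a median and mean of -0.01 and -0.00 and a test pointing up, and 1 of 20 members rose over all genes, or 2 with 1 falling over the list alone. DUSP6 was at 162 ± 7.63 and 159 ± 9.86 CPM (n = 3, adjusted p = 0.903), SPRY4 at 16.6 ± 0.793 and 20.1 ± 1.27 CPM (0.0686, and 0.0356 with no filter, in a range of 0.0356 to 1), and FGFR2 at 14.2 ± 1.32 and 16.6 ± 0.839 CPM (0.269). FGFBP1, which encodes a carrier of FGF ligands, fell 1.31-fold from 318 ± 0.604 CPM (adjusted p = 7.77e-07). In the cell cycle list 1 of 28 genes fell, or 8 over the list alone (3.85e-11, and 0.34 estimated). MKI67 was at 21.1 ± 3.47 and 16.5 ± 2.50 CPM (0.0954); its p ranged from 0.000957 with no filter to 1 over the alternatives and was 0.0153 without LPM library 1. KRT5 was at 4323 ± 62.9 and 4058 ± 73.4 CPM (0.305). The surface glycoprotein gene THY1 fell 1.28-fold (adjusted p = 2.35e-05) and BPIFA1, a secreted airway and oral protein gene, rose 1.41-fold (4.38e-05). Camera with the preset value also called lower the cholesterol synthesis list (0.00445, and 0.168 estimated), the unfolded protein response list (0.0124, and 0.485 estimated) and the lysosome list (0.0202, and 0.242 estimated), with 0, 0 and 1 gene called by edgeR and 0, 0 and 2 over the list alone. The fry test called the first (0.025) and neither the second (0.268) nor the third (0.0736). The unfolded protein list was lost without LPM library 1 (0.204), and it and the lysosome list without library 3 lacking FGF10 (both 0.106). Of the 37 lists tested 10 were called. Without the replicate block, limma camera with an estimated correlation called the secretory and oxidative stress lists.

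The count of 254 genes was 125 without LPM library 2 and 128 without library 1 lacking FGF10. In a fit of all 6 groups edgeR called 0 genes, with 52 at an unadjusted p under 0.05. That fit estimates each gene's spread over all libraries, including those of different pigs. On this experiment alone DESeq2 called 218 genes and limma-voom 236.

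The CQ experiment asked how organoids moved from LPM to CQ differed from organoids kept in LPM, with 3 libraries per arm and no recorded day for the LPM arm. With the preset correlation, the cell cycle, glycolysis, ERK target and cytokine lists were called lower in CQ and the lysosome list higher. None of these calls held with an estimated correlation (adjusted p = 0.0713, 0.195, 0.288, 0.195 and 0.305). DUSP6 (chromosome 5, 93303058 to 93307510) fell 200.0-fold, from 352 ± 28.7 to 1.77 ± 1.31 CPM (SD, n = 3 each, log2 fold change -7.64, SE 0.38, adjusted p = 1.06e-06). The floor of the CQ group was 0.811 CPM, so the size of this fall is uncertain. GPNMB, a lysosomal membrane glycoprotein gene (chromosome 9, 92037428 to 92071501), rose 421-fold from 0.126 ± 0.104 to 54.9 ± 11.8 CPM (SE 0.37, adjusted p = 5.29e-07). Of 13827 genes tested 6625 were called, 3189 higher and 3436 lower in CQ, and 1332 of the higher and 2211 of the lower changed at least 2-fold.

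The CQ libraries also stood apart in library makeup. RN5-8S, which lies on an unplaced scaffold, was at 2.701 ± 0.501 CPM in LPM and 1981 ± 154 CPM in CQ (n = 3, 726-fold, adjusted p = 1.74e-08). Genes with 1 to 4 counts numbered 559, 231 and 437 in the CQ libraries and genes with 5 to 9 counts 1206, 432 and 895, whereas the LPM libraries held 2633, 2677 and 2687 of the former and 970, 998 and 1011 of the latter. The most frequent count above 0 was 8, 14 and 10 in the CQ libraries and 1 in each of the other 19 libraries of the series. Genes at 0 counts in CQ are therefore given against the higher floor of that group. Other low CQ levels are given as counted, and the size of falls to a few CPM is uncertain.

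**Figure D2:**
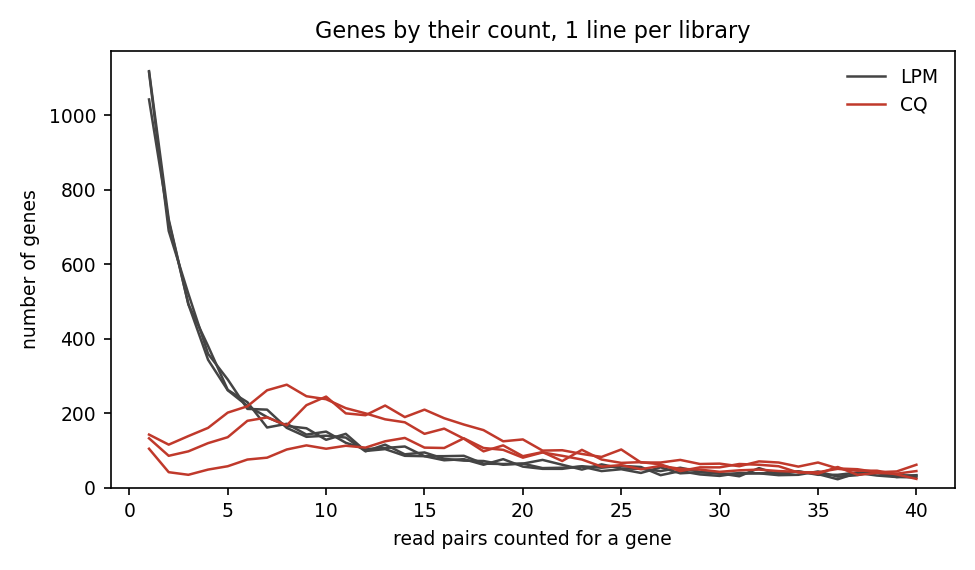
Number of genes at each count of read pairs from 1 to 40 in the CQ experiment, with 1 line per library, grey for LPM and red for CQ. The LPM lines are highest at 1 read pair, and the CQ lines peak at 8, 14 and 10.

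All 28 cell cycle genes fell (camera adjusted p = 3.48e-10, and 0.0713 with an estimated correlation). MKI67 fell 29.8-fold from 79.0 ± 18.998 to 2.60 ± 3.39 CPM (n = 3, adjusted p = 0.000634), the topoisomerase gene TOP2A 55.9-fold from 142 ± 19.02 CPM and NUSAP1 4.92-fold. Of 20 FGF and ERK targets 18 fell and 1 rose (2.77e-07, and 0.288 estimated). SPRY1, a feedback inhibitor of FGF signalling, fell 79.8-fold from 151 ± 17.7 CPM (adjusted p = 1.12e-07) and EGR1, an immediate early gene, 7.79-fold. SPRY4 had 894 counts in LPM and 16 in CQ (adjusted p = 0.00147), the latter under the CQ floor of 38.2 counts. FGFR3 fell 3.26-fold (7.45e-05). FGFR2 fell 1.89-fold (0.0195), a call lost without LPM library 1 (0.0687), CQ library 1 (0.0616) or CQ library 3 (0.0563), over a range of 0.00144 to 0.0687. All 21 glycolysis and hypoxia genes fell (5.26e-13, and 0.195 estimated), among them NDRG1, from 1523 ± 109 to 129 ± 4.66 CPM (11.8-fold, adjusted p = 1.12e-07), and the oxygen sensor gene EGLN3 (9.91-fold). All 11 tested cytokine and NF-kB targets fell, with a median log2 change of -5.62, or -4.84 with 2 genes at their bound (0.000164, and 0.195 estimated). The chemokine gene CXCL2 fell 49.3-fold from 54.8 ± 6.02 CPM (adjusted p = 2.09e-07). The prostaglandin synthase gene PTGS2 had 7162 counts in LPM and 20 in CQ, the latter also under the CQ floor.

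Of 20 lysosome and autophagy genes 13 rose and 2 fell (adjusted p = 0.0008, and 0.305 with an estimated correlation). Beside GPNMB these included ATP6V0D1, a subunit of the proton pump that acidifies lysosomes, from 44.0 ± 3.57 to 169 ± 4.79 CPM (3.85-fold, n = 3, adjusted p = 2.26e-06), while WIPI1 fell 4.64-fold. HPGD, which inactivates prostaglandins, rose 113-fold to 84.2 ± 3.83 CPM (adjusted p = 1.34e-07), the autophagy gene ATG9B 86.1-fold and TAGLN, an actin-binding protein gene, 81.0-fold to 172 ± 33.1 CPM. Of 9 simple and secretory epithelium genes 8 fell and 1 rose, with a median of -2.86, or -2.48 with 2 genes at their bound (0.00295, and 0.195 estimated); WFDC2 fell 23.2-fold from 200.1 ± 33.5 CPM (adjusted p = 1.55e-06) and LCN2 6.94-fold. Of 14 lipid storage and retinoid genes 9 fell and 1 rose (0.00329, and 0.195 estimated). ALDH1A1, a retinaldehyde dehydrogenase, fell 13.7-fold from 1087 ± 65.8 CPM and the desaturase gene SCD 5.60-fold, while the fatty acid carrier gene FABP5 rose 22.7-fold to 375 ± 16.0 CPM. The vitamin D hydroxylase gene CYP24A1 was at 48.0 ± 7.20 CPM in LPM and at 0 in CQ (at least 58.4-fold lower), and so were CCL2 (at least 28.6-fold) and A4GALT (at least 35.4-fold).

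**Figure D3:**
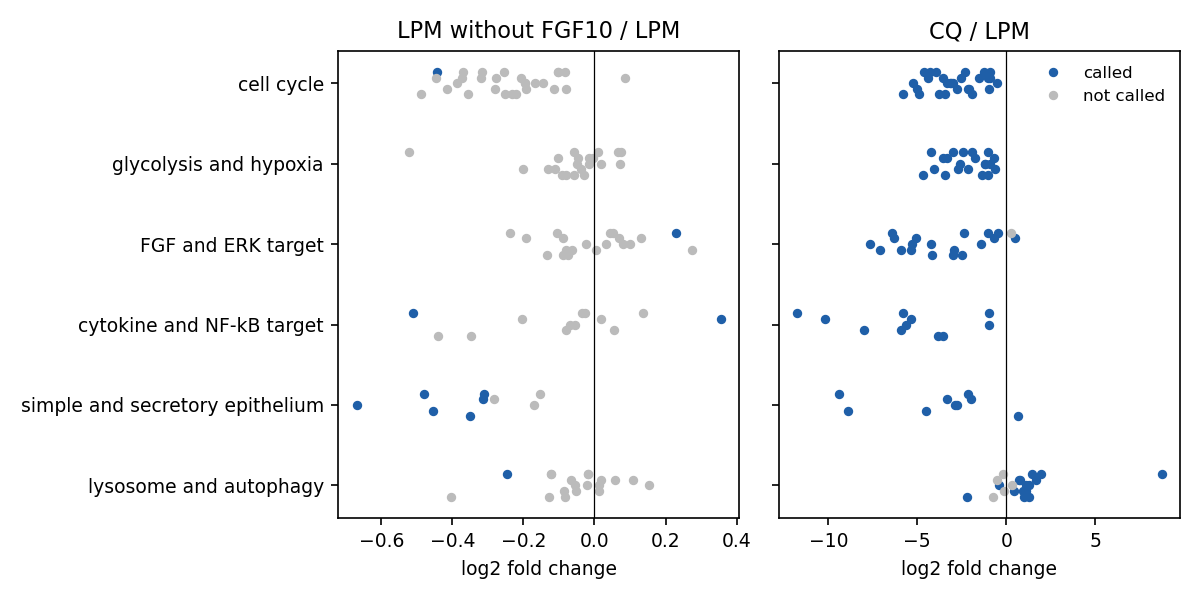
Log2 fold change of each tested member of 6 gene lists for LPM without FGF10 against LPM and for CQ against LPM, with called genes in blue and others in grey and a separate horizontal scale in each panel. In the CQ panel the 28 cell cycle and 21 glycolysis genes lie below 0 and 13 of 20 lysosome genes are called above it.

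Camera called no taste list, whereas fry called the stem and progenitor list (adjusted p = 0.000653) and the receptor list (0.000266) lower. In the stem and progenitor list 4 of 10 members rose and 5 fell, with a camera adjusted p of 0.50, and in the receptor list 1 of 4 fell (0.499). SOX2 fell 3.01-fold from 193 ± 14.9 to 63.9 ± 8.17 CPM (n = 3, adjusted p = 1.73e-05), LGR6 3.21-fold from 13.9 ± 1.35 CPM (0.000873, and 0.0617 in the fit of all 6 groups, in a range of 4.65e-07 to 0.0617), and SHH went from 21.8 ± 2.16 CPM to 0 (at least 26.7-fold lower). HES6 rose 1.99-fold to 76.3 ± 10.8 CPM (0.00296). LGR5 had 0 counts in LPM and 23 in CQ, and GLI1 had 1 and 16, all under the floor of the CQ group. TRPM5 was at 1.30 ± 0.488 and 1.35 ± 1.83 CPM (adjusted p = 0.983), TAS1R3 at 18.9 ± 4.13 and 19.7 ± 3.09 CPM (0.852) and ENTPD2 at 3.32 ± 0.733 and 2.95 ± 0.400 CPM (0.78). PLCB2 had 4 and 8 counts and GNAT3 30 and 0, and neither was tested. PKD2L1 fell from 194 counts to 6 (adjusted p = 0.013), a CQ count under the floor of that group. This call was lost without any 1 of LPM libraries 1, 2 and 3 (0.0751, 0.0584 and 0.0511, range 0.000165 to 0.0751). The calcium release channel gene ITPR3 rose 1.92-fold to 310.0 ± 25.7 CPM (0.00454).

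In the beta cell transcription factor list 3 of 7 members rose and 1 fell, and the list was not called by camera (adjusted p = 0.533) but was by fry (0.0261). MAFA, an activator of the insulin gene (chromosome 4, 1090018 to 1093600), rose 16.9-fold from 0.635 ± 0.0899 to 10.8 ± 4.70 CPM (n = 3, SE of log2 0.45, adjusted p = 0.000114), from 41 to 503 counts. At the estimated 12.73 reads per molecule these 503 counts stand for far fewer molecules, so the size of this rise is uncertain. Genomic DNA was not tested for in the CQ libraries. FOXA2 fell 1.49-fold from 96.1 ± 2.02 CPM (0.00433). Of 9 insulin processing and secretion genes 2 rose and 3 fell, or 2 and 4 over the list alone (0.898). The syntaxin gene STX1A rose 6.04-fold to 13.8 ± 4.09 CPM (0.000221) and PAM, which amidates peptide hormones, 1.69-fold to 269.8 ± 19.2 CPM (0.000731).

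The basal, suprabasal and taste bud epithelium lists were not called by camera (0.100, 0.898 and 0.987), though the basal list was called lower by fry (0.000717) and without LPM library 3 (0.049). KRT6A, a keratin of activated epithelium, rose 3.22-fold to 3431 ± 94.4 CPM (n = 3, adjusted p = 1.55e-06), KRT8 rose 1.61-fold (0.000858, and 0.0903 in the fit of all 6 groups, in a range of 6.13e-09 to 0.0903) and the tight junction gene CLDN4 2.17-fold, while KRT4 fell 8.35-fold and KRT18 4.57-fold. KRT5 was at 1912 ± 187 and 2201 ± 163 CPM (0.124; range 0.0135 without LPM library 3 to 0.537, and 0.0249 with library size alone). TP63, the basal epithelial factor, fell 4.89-fold from 136 ± 9.50 CPM (3.24e-06). Of 12 Wnt targets 5 rose and 4 fell; CCND1 fell 12.0-fold from 93.0 ± 8.36 CPM (2.88e-06), APCDD1 rose 3.004-fold (8.33e-05) and AXIN2 rose 1.58-fold (0.0104), a call lost without LPM library 2 (0.0599) and in the fit of all 6 groups (0.136, the highest of its range from 0.00326). Among markers of other cell types, THY1 rose 32.5-fold from 8.71 ± 1.13 to 283 ± 26.0 CPM (1.12e-07) and the nerve growth factor receptor gene NGFR fell 19.3-fold from 603 ± 23.5 CPM (9.99e-07), and neither the fibroblast list (0.84) nor the nerve list (0.804) was called. Of 36 lists tested 7 were called, and limma camera with an estimated correlation called 0, against 23 by fry. The count of 6625 genes was 4933 without LPM library 2 and 5423 after the counts were divided by the estimated reads per molecule, a fit chosen after the data were seen, in which 9910 genes were tested and 5086 of the same genes called.

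To ask whether either medium moved organoids toward papillae, the genes that set passage 1 organoids apart were tested in the media comparisons, which share no library with them. Of the 500 genes most clearly higher in organoids than in papillae, 496 were tested in CQ, where 245 fell and 68 rose (median log2 change -0.38, camera adjusted p = 7.71e-06, and 0.312 with an estimated correlation). Of the 500 genes most clearly lower in organoids only 149 were tested in CQ, so the result covers a minority of that set. Of these 149 genes 35 rose and 26 fell, with a median of -0.08 and a camera test pointing up (adjusted p = 0.670). Without FGF10 500 genes of the higher set and 174 of the lower set were tested. Neither set was called (0.670 and 0.575), with 5 and 1 genes rising and 15 and 5 falling. Across genes, Spearman's correlation with the difference between organoids and papillae was -0.142 for CQ (13439 genes) and -0.0378 for FGF10 withdrawal (14084 genes), and genes are not independent replicates.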

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

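The test of few molecules read many times against the fewer detected genes and the splits that part every pig were chosen after the result was seen, and the fits for CQ without ribosomal RNA and on genes of at least 100 CPM were added after those libraries had been examined. Among 146 values 6 lay further from the other libraries of their group than a Dixon test allows, where about 7 were due by chance, and 3 of them were in the organoids of pig 4. MKI67 was at 283 CPM in the organoids of pig 4 and at 4.60 to 32.9 CPM in the other 4. In the same library IGSF23 was at 96.5 CPM (others 54.1 to 64.7) and ZNRF3 at 82.9 CPM (others 41.5 to 49.9). In the organoids of pig 5 ADM was at 308 CPM (others 68.6 to 124) and SCG5 at 6.67 CPM (others 2.08 to 3.25), and in those of pig 2 FOXA2 was at 161 CPM (others 86.8 to 103).

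Fewer genes were detected in CQ libraries, at most 16005. Fewer counts per library did not account for this, because LPM libraries thinned to the depth of the shallowest CQ library still detected at least 17161. The median ratio of variance to mean among low-count genes was 12.7 in CQ and 1.75 in LPM, which is consistent with few molecules read many times. Of genes at a mean of at least 100 CPM 68.9% were called. Noise confined to low-count genes could therefore not account for all called genes. A bias shared by all CQ libraries could also move abundant genes, and this test cannot exclude it. Without the ribosomal scaffold, abundant and mitochondrial genes 6576 genes were called, so the counts of these genes themselves did not make the calls. Removing them does not test whether ribosomal RNA marks a difference in library makeup. How many cells each CQ library came from is not given in the sources used here.

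In the type I, II and III taste cell lists 19 members were called lower in organoids than in papillae. Scaling could not explain this, because 17 of these 19 stayed lower both with library size alone and without abundant genes, AVIL and CALHM3 being lost with library size alone. Genomic DNA in papilla libraries, extracted without DNase, could not either, since 38 genes of other organs had a median CPM per kb that was 0.785% of that of these members. A smaller share of mature taste cells in organoids was not tested apart from lower expression per cell, and the extraction kit differed with the group. Some of the 19 members, such as NCAM1 and SCG2, are also neuronal genes. In the same libraries 13 of 15 nerve and Schwann cell genes and 8 of 8 gland genes fell. Loss of such other tissue was not tested apart from loss of taste cells either.

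Because pigs pair papillae and organoids, the real split was set beside the splits that also part the libraries of every pig. These are 16, too few for a share under 0.05, and the real 1 gave 11011 genes (highest other 0). With 10 splits each, the media experiments also had too few for a share under 0.05; the real 1 of 10 gave 254 genes for FGF10 (highest other 7) and the real 1 of 10 gave 6625 for CQ (highest other 0).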

How the results depend on the processing

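Among 213 pairs of a named gene and a comparison, and among the lists, no alternative reversed a call. Of these pairs 163 had the same outcome, called or not, in every alternative. For organoids against papillae 11011 genes were called, 10443 to 11577 without any 1 library and 10679 with the pig as a block. Gene lists called numbered 18 with the preset correlation, 0 with an estimated one, 34 by fry, 19 with the block and 17 to 20 without any 1 library. For LPM without FGF10 the 254 genes became 429 with no filter, 0 in the fit of all 6 groups, 234 with the replicate block and 125 to 294 without any 1 library, and the 10 lists became 2 with an estimated correlation, 5 by fry, 12 with the block and 8 to 13 without any 1 library. For CQ the 6625 genes became 6120 with the block, 4933 to 7112 without any 1 library, and 1384 when only the 2008 genes at a mean of at least 100 CPM were tested, an alternative chosen after the data were seen. The 7 CQ lists became 0 with an estimated correlation, 23 by fry, 8 with the block and 7 to 9 without any 1 library. In CQ the genes higher in organoids had an adjusted p of 0.3122 with an estimated correlation and 1.636e-08 to 3.91e-05 without any 1 library. The cause of these shifts was not tested.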

Other observations

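Single hormone and glucose genes also differed between papillae and organoids. Of 6 gut hormone genes 3 fell and 1 rose, and the list was not called by camera (adjusted p = 0.261, and 0.437 with an estimated correlation) but was by fry (0.000111). The neuropeptide gene VIP had 2727 counts in papillae and 1 in organoids (ratio 4145, 95% interval 743 to 163782), and GAL was at 16.4 ± 10.3 CPM in papillae and at 0 in organoids (at least 727-fold lower, n = 5 each), both also being nerve transcripts, in libraries where nerve markers fell. Of 11 glucose sensing genes 7 rose and 2 fell in organoids, with the insulin receptor substrate gene IRS2 4.20-fold higher (edgeR adjusted p = 1.94e-05) and the hexokinase gene HK2 5.51-fold higher (1.39e-05), and the list was not called by camera (0.094, and 0.274 with an estimated correlation) but was by fry (0.000142).

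In CQ, 5 of 20 unfolded protein response genes rose and 7 fell, with a median log2 change of -0.07, a mean of 0.03 and a camera test pointing down (adjusted p = 0.898). The stress-induced genes TRIB3 and CHAC1 rose 5.25-fold to 53.5 ± 7.08 CPM (n = 3, edgeR adjusted p = 1.96e-05) and 4.42-fold, while XBP1, a factor of the unfolded protein response, fell 2.47-fold from 334 ± 11.2 CPM (1.15e-05). Of 16 oxidative stress genes 7 rose and 5 fell, or 8 and 6 adjusted over the list alone, with a median of 0.07, a mean of -0.86 and a test pointing up that camera did not call (0.680) and fry did (0.000349). The redox genes SRXN1 and TXNRD1 rose 3.11-fold and from 22.8 ± 1.73 to 86.7 ± 11.3 CPM. Of 14 Notch pathway genes 8 fell and 3 rose, with the target HEY1 34.6-fold and the ligand JAG1 6.05-fold lower, and the list was not called by camera (0.115) but was by fry (0.000513).

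No test in this part was chosen after its result was seen. Of 63 genes that varied among pigs in both groups, 11 had levels correlated at 0.9 or more between papillae and organoids under the real pairing, against a median of 1 over all other pairings of these pigs, of which 1 also reached 11. This is consistent with differences between animals that were kept in culture. ASPG, chosen after its values were seen, was at 28.6, 7.07, 20.7, 5.41 and 18.9 CPM in papillae of pigs 1 to 5 and at 42, 0.492, 30.2, 0.409 and 15.9 CPM in their organoids.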
